A study of Mus musculus with 2 samples.

How the data were processed

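Single-cell RNA sequencing was analysed for 2 libraries of mouse bone marrow culture cells, 1 library per group. Per the labels' protocols, femur bone marrow of C57BL/6 mice was cultured for 5 days with GM-CSF (granulocyte-macrophage colony-stimulating factor) at 40 ng/mL. In the coculture group, human mesenchymal stromal cells (MSC) sat in transwell inserts with 0.4 µm pores, at 1 MSC to 5 bone marrow cells, after 24 h of preincubation. Cells were sorted with a viability dye, as CD11b-high Ly6C-high cells from the culture without MSC and as CD11b-mid Ly6C-mid cells from the coculture, and the protocols name different base media (RPMI and DMEM). Libraries were made with a droplet kit that reads the 3' ends of transcripts and tags each molecule with a unique molecular identifier (UMI).

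The files hold raw UMI counts per gene and cell barcode, deposited by the authors as sparse matrices of 47729 genes, not normalized. Their software version is 3.1.0 per the file headers. Reads were processed with Cell Ranger and bcl2fastq against the mouse build mm10, per the submitters' processing notes. The annotation release and the rule that separated cells from empty droplets are not given in the sources used here. Gene symbols came from the files, and 47224 of the 47729 gene identifiers were in the GENCODE M21 table, whose GRCm38 positions (the same build as mm10) were used. For the 126 symbols carried by more than 1 identifier, the first kept the plain symbol. The counts come from reads on 1 end of the transcript, so genes of near-identical copy families (Ly6c1 and Ly6c2, the Klk1b, Iglc, Hbb, Stfa and Lilr families) are uncertain where reads could be shared. Transcripts of the human MSC were not analysed here.

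The library without coculture held 28294186 UMIs over 2180 barcodes and the coculture library 29217182 UMIs over 3134 barcodes. Barcodes with at least 500 genes and at most 10% mitochondrial UMIs were kept. Scrublet, run per library in scanpy 1.11.5, then called 0 and 5 barcodes, 0.104% of those left, so doublets were essentially not removed and any droplet holding more than 1 cell remained in the data. After these steps 1817 and 3000 cells were kept, with 27784963 and 29019723 UMIs. UMIs were summed over the kept cells of a library, or of 1 class in a library, and given as CPM, the count scaled to a common total, from that sum. The log2 ratio is the coculture CPM over the CPM without coculture. A gene with 0 UMIs in 1 library took the floor of 3 UMIs of that library, which was 0.108 CPM without coculture and 0.103 CPM in the coculture. Ratios written as at least are against this floor, and the lower bound of their exact interval is smaller (24837-fold for Epx over all cells, against 30541-fold). Genes were counted as measured at a CPM of 10 or more in either library.

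CPM values carry exact Poisson 95% intervals, ratios the exact conditional binomial interval, and shares of cells exact (Clopper-Pearson) binomial intervals. The limit given for a share of 0 is 3 cells over the cells counted, which is below the Clopper-Pearson bound (0.165% and 0.203% for 0 of 1817). All of these cover counting error only. The CPM and ratio intervals treat UMIs as independent, so they are too narrow where a few cells hold most of a gene's UMIs. With 1 library per group there is no replicate, so no test was run and no p-value or standard error is given. The sort gate, the coculture, the named medium and the library differ together, so every comparison is between these 2 libraries and not between conditions.

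Cells of both libraries were clustered together on counts scaled to 10000 per cell and log-transformed, with 2000 variable genes, 30 principal components, 15 neighbours and the Leiden method (igraph 0.11.9) at resolution 0.8. Clusters were named from 16 marker sets: monocyte, macrophage, neutrophil, granulocyte-monocyte progenitor, dendritic cell, mature dendritic cell, plasmacytoid dendritic cell, B cell, plasma cell, T or NK cell, basophil or mast cell, eosinophil, erythroid cell, megakaryocyte or platelet, osteoclast, and stromal or endothelial cell. The B cell and plasma cell sets were pooled as B lineage. Each cluster took the set with the highest mean log2 fold over all other cells (each marker at 20 CPM or more, with a pseudocount of 5 CPM and folds limited to between 0 and 5), and was called "-like" if at least 3 markers were 2-fold higher and its 10 leading genes held no more markers of another set than of its own. A tie of 1 marker each was resolved by the score, and a tie of more left the cluster unnamed. This scoring rule was set after the data were seen, while the markers, the gene lists and most alternative settings were fixed before the data were examined.

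The 30 gene lists hold, with the marker sets, 672 genes, of which 670 were in the files. They cover gate markers, classical monocyte genes, MHC class II and class I presentation, costimulation and dendritic maturation, suppressor-associated genes, inhibitory receptors and ligands, the type I interferon response, inflammatory cytokines and inflammasome, chemokines, alternative activation, complement and efferocytosis, lysosome and proteolysis, lipid handling, cholesterol biosynthesis, glycolysis and hypoxia, oxidative phosphorylation, iron and oxidative stress, unfolded protein and amino acid stress, immediate early and heat shock genes, NADPH oxidase and granule enzymes, GM-CSF and STAT5 signalling, the M-CSF axis and macrophage regulators, Fc and pattern recognition receptors, prostaglandin synthesis and reception, ribosomal proteins, mitochondrially encoded genes, sex-linked genes, S phase and G2/M phase. For each list the measured members at least 2-fold higher or lower were counted, and the median log2 ratio was placed as a percentile among 10000 random lists of the same size matched on mean expression over 20 bins, as a description of these libraries.

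Genes were named by a rule of size. Among genes at 100 CPM or more in either library, leaving out ribosomal protein, mitochondrially encoded and predicted genes, the 12 highest and 12 lowest log2 ratios were taken over all cells, and the 8 highest and 8 lowest within a class that held at least 100 cells in each library. From each list, up to 4 members with the largest absolute log2 ratio at 20 CPM or more were taken, with the member of highest CPM. Gate genes were always given, and each cluster was described by its 5 leading genes. A gene named outside this rule is marked as chosen after its values were seen. A few genes that the rule names are not reported here.

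For shares of cells with a UMI and for cycling cells, every cell was thinned to 2072 UMIs, the 10th percentile of kept cells in the shallower library, which left out 151 and 300 shallower cells and kept 1666 and 2700. A cell was counted for a cycling list if it held at least 2 UMIs of that list. The alternatives fixed in advance were all deposited barcodes, stricter filters (1000 genes, 5% mitochondrial UMIs), called doublets kept, the 5% of cells with most UMIs left out, TMM factors (edgeR 4.0.16 in R 4.3.3), equal weight for each cell, the 50 most abundant genes left out of the total, a minimum of 50 CPM, a minimum of 10 UMIs over both libraries, resolutions 0.4 and 1.2, 1000 variable genes, clustering without S and G2/M genes, clustering of thinned cells, thinning to 1036 UMIs or not at all, and 1 or 4 UMIs for cycling cells. Another pair of alternatives was chosen after seeing the data, namely clusters with tied markers left unnamed, and clustering without the genes named within the neutrophil-like class and the suppressor-associated list.

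The sums, intervals and list percentiles were tested on simulated data. In counts drawn for 8043 genes from the means over all cells, with 200 genes changed, the true ratio lay inside the interval for 100%, 96%, 90% and 94% of the 50 genes each at log2 ratios of 1, -1, 2 and -2, and for 95.2% of the 7843 unchanged genes. The counts were independent Poisson draws of library sums, with no cells simulated. Coverage near 95% was therefore set by the draws, and it cannot show how the intervals behave for UMIs clumped in few cells. A list raised 2-fold came at percentile 100, and 1 other list of the 30 fell outside the central 95%. Computation used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0 and matplotlib 3.10.9.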

Results

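The data are UMI counts from 2 single-cell libraries of sorted mouse bone marrow culture cells, made to characterise at the single-cell level the myeloid suppressor cells that form when bone marrow is cultured with GM-CSF beside human MSC. The library without coculture came from CD11b-high Ly6C-high cells, and the coculture library from CD11b-mid Ly6C-mid cells of the culture with MSC inserts. CD11b is an integrin chain of myeloid cells encoded by Itgam, and Ly6C is a surface protein of monocytes and granulocytes encoded by Ly6c1 and Ly6c2. The kept cells numbered 1817 without coculture and 3000 in the coculture. Their median was 7016 UMIs and 2124 genes per cell without coculture, and 6026 UMIs and 1959.5 genes in the coculture. Barcodes over 10% mitochondrial UMIs made up 15.5% (14.0 to 17.1%) of the library without coculture and 2.87% (2.32 to 3.52%) of the coculture library, and they were left out. Each group has 1 library, so no difference has a replicate check, and intervals cover counting error only.

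Summed over all cells, the genes behind the sort gates were both lower in the coculture library, which is the direction of the gates. Itgam (ENSMUSG00000030786, chromosome 7, 128062640 to 128118491 in GRCm38, the same build as mm10) stood at 351 CPM (344 to 358) without coculture and 144 CPM (140 to 149) in the coculture, 2.43-fold lower. Ly6c2 (ENSMUSG00000022584, chromosome 15, 75108158 to 75111970) stood at 344 and 96.5 CPM, a log2 ratio of -1.83 (-1.89 to -1.77). Its neighbour Ly6c1 had only 8 and 3 UMIs, and the granulocyte gene Ly6g 25.8 and 16.2 CPM (log2 ratio -0.67). As a list, the gate markers had 3 measured members, 0 higher, 2 lower and 1 between, with a median log2 ratio of -1.28 at percentile 2.64 of random lists. These genes were used to choose the cells, directly or as near relatives, and are a check of the labels rather than a finding. Within neutrophil-like cells Itgam was higher in the coculture, at 312 CPM without coculture and 496 CPM in the coculture. Its lower sum over all cells therefore does not show less Itgam in like cells.

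The sorts held different cells. Without coculture, 63.6% of cells (1155; 61.3 to 65.8%) were neutrophil-like and 31.9% (579; 29.7 to 34.1%) macrophage-like. In the coculture library 17.6% (529; 16.3 to 19.0%) were neutrophil-like, 30.3% (908; 28.6 to 31.9%) B lineage-like, 15.6% (467; 14.3 to 16.9%) eosinophil-like and 13.3% (400; 12.1 to 14.6%) basophil or mast cell-like. A further 9.47% (284; 8.44 to 10.6%) were mature dendritic cell-like, 5.33% (160) megakaryocyte or platelet-like, 3.87% (116) granulocyte-monocyte progenitor-like and 3.17% (95) T or NK cell-like. Only 1 of the 3000 coculture cells (0.0333%) was macrophage-like at the main settings. At resolution 1.2 an unnamed cluster of 127 coculture cells and 25 without coculture was led by C1qa, Ccl24 and Plet1. Its 10 leading genes held 3 macrophage and 0 dendritic cell markers, but the dendritic cell set scored highest in it, with 10 markers at least 2-fold higher. The smaller classes depend on the settings. At resolution 0.4 no cluster was named megakaryocyte or platelet-like or progenitor-like, and an unnamed cluster of 278 coculture cells was led by Gp1bb, Cd34, Itgb3 and Elane, while stricter filters left no T or NK cell-like cluster.

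**Figure D1:**
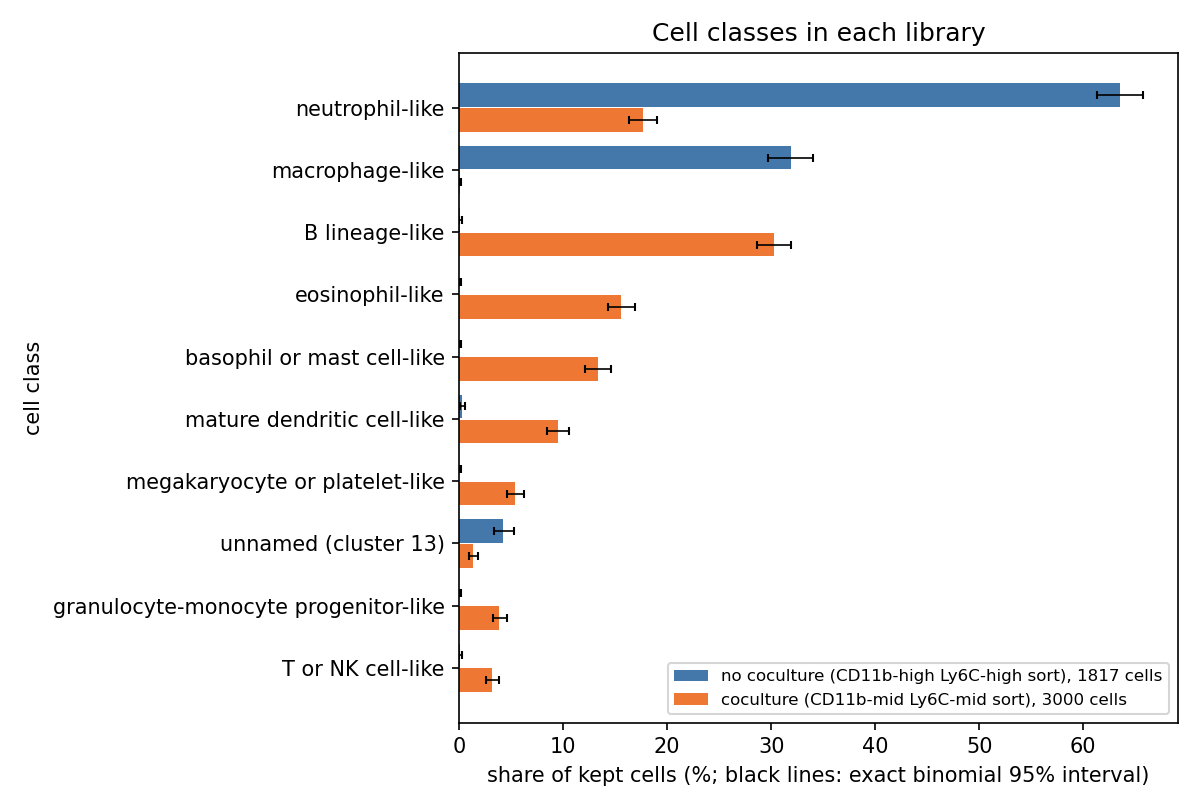
Share of kept cells (%, horizontal axis) in each cell class (vertical axis) for both libraries, with exact binomial 95% intervals as black lines. Neutrophil-like and macrophage-like cells fill the library without coculture, at 63.6% and 31.9%, while B lineage-like, eosinophil-like and basophil or mast cell-like cells are seen almost only in the coculture library.

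Conversely, 0 of 1817 cells without coculture were eosinophil-like, basophil or mast cell-like, megakaryocyte or platelet-like or progenitor-like, which allows a share of up to 0.165% (3 cells) for each. B lineage-like and T or NK cell-like cells numbered 1 each there, and mature dendritic cell-like cells 4 (0.220%). Cluster 13, led by Ptx3, Asgr2, Ccl17, Ccl4 and Ccl24, stayed unnamed because its leading genes held as many macrophage as dendritic cell markers, and it took 4.24% of cells (77) without coculture and 1.33% (40) in the coculture. At the main settings no cluster was named from the monocyte, dendritic cell, plasmacytoid dendritic cell, erythroid cell, osteoclast, or stromal or endothelial cell markers. The macrophage-like name does not mean that monocyte genes were absent. Of 11 monocyte markers, clusters 6 and 10 had 9 and 10 at 20 CPM or more, with 2 in each at least 2-fold higher than in other cells. Macrophage-like cells held 96.3% of the Ccr2 and 67.4% of the Ly6c2 UMIs without coculture, but 40.2% of the Chil3 and 18.7% of the Plac8 UMIs. A dendritic cell-like cluster appeared at resolution 1.2 (53 cells without coculture, 0 in the coculture) and without the 5% of cells with most UMIs (107 and 37). A cluster took the stromal or endothelial cell-like name when S and G2/M genes were kept out of the clustering (135 and 48) and with stricter filters (74 and 24), although only 9 kept cells, all of them in the coculture, held at least 10 UMIs over 6 matrix genes, so the name does not describe most of its cells. The 2 gates differ in the CD11b and Ly6C level they take, so the shares describe the sorts, and a cluster filled by 1 library may stand for that library as well as for a type. Leaving unnamed the clusters whose leading genes hold as many markers of another set lowered the neutrophil-like share without coculture from 63.6 to 35.7%.

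Most clusters were led by well-known lineage genes. Leading genes help to define the clusters, so where a cluster belongs to 1 library its leading genes also differ between the libraries. The eosinophil-like cluster 4 was led by the granule protein genes Prg2, Epx and Prg3, and the basophil or mast cell-like clusters 8 and 16 by the protease genes Tpsb2, Mcpt8 and Gzmb. The B lineage-like clusters were led by Ighd, Bank1 and Iglc2 (cluster 1) and by Igha, Jchain and Shisa8 (cluster 7). With all deposited barcodes, Igha and Jchain instead led an unnamed cluster of 89 cells without coculture and 44 in the coculture. These genes may therefore not describe all of cluster 7. Mature dendritic cell-like cluster 9 was led by Ccl5, the homing receptor gene Ccr7 and Fscn1, which encodes the actin-bundling protein fascin. The megakaryocyte or platelet-like cluster 12 was led by the glycoprotein gene Gp1bb and Itgb3, progenitor-like cluster 14 by Elane, Prtn3 and Mpo, and T or NK cell-like cluster 15 by Trbc2, Cd8b1 and Cd3d. Macrophage-like clusters 6 and 10 were led by Wfdc17 and the mannose receptor gene Mrc1. Cluster 10 (218 cells) also carried the neutrophil markers S100a8 at 9980 CPM and S100a9 at 11564 CPM, against 274 and 126 CPM in cluster 6. Its median depth was 38956.5 UMIs, against 19873.5 in cluster 6. Droplets with more than 1 cell were not removed, and whether cluster 10 holds such droplets was not tested. Among the neutrophil-like clusters, Slfn1 and Lilra6 led cluster 2 (507 cells without coculture, 3 in the coculture), Asprv1 and Acta2 cluster 5 (463 and 3), Arg1 and Cxcl3 cluster 3 (5 and 491), and the granule genes Ltf, Camp and Ngp cluster 11 (180 and 32). Clusters 2 and 3 held only 1 neutrophil marker each among their 10 leading genes. The class was thus held by clusters 2, 5 and 11 in the library without coculture and mainly by cluster 3 in the coculture, and cluster 11 was the only neutrophil-like cluster with over 10 cells of each library.

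**Figure D2:**
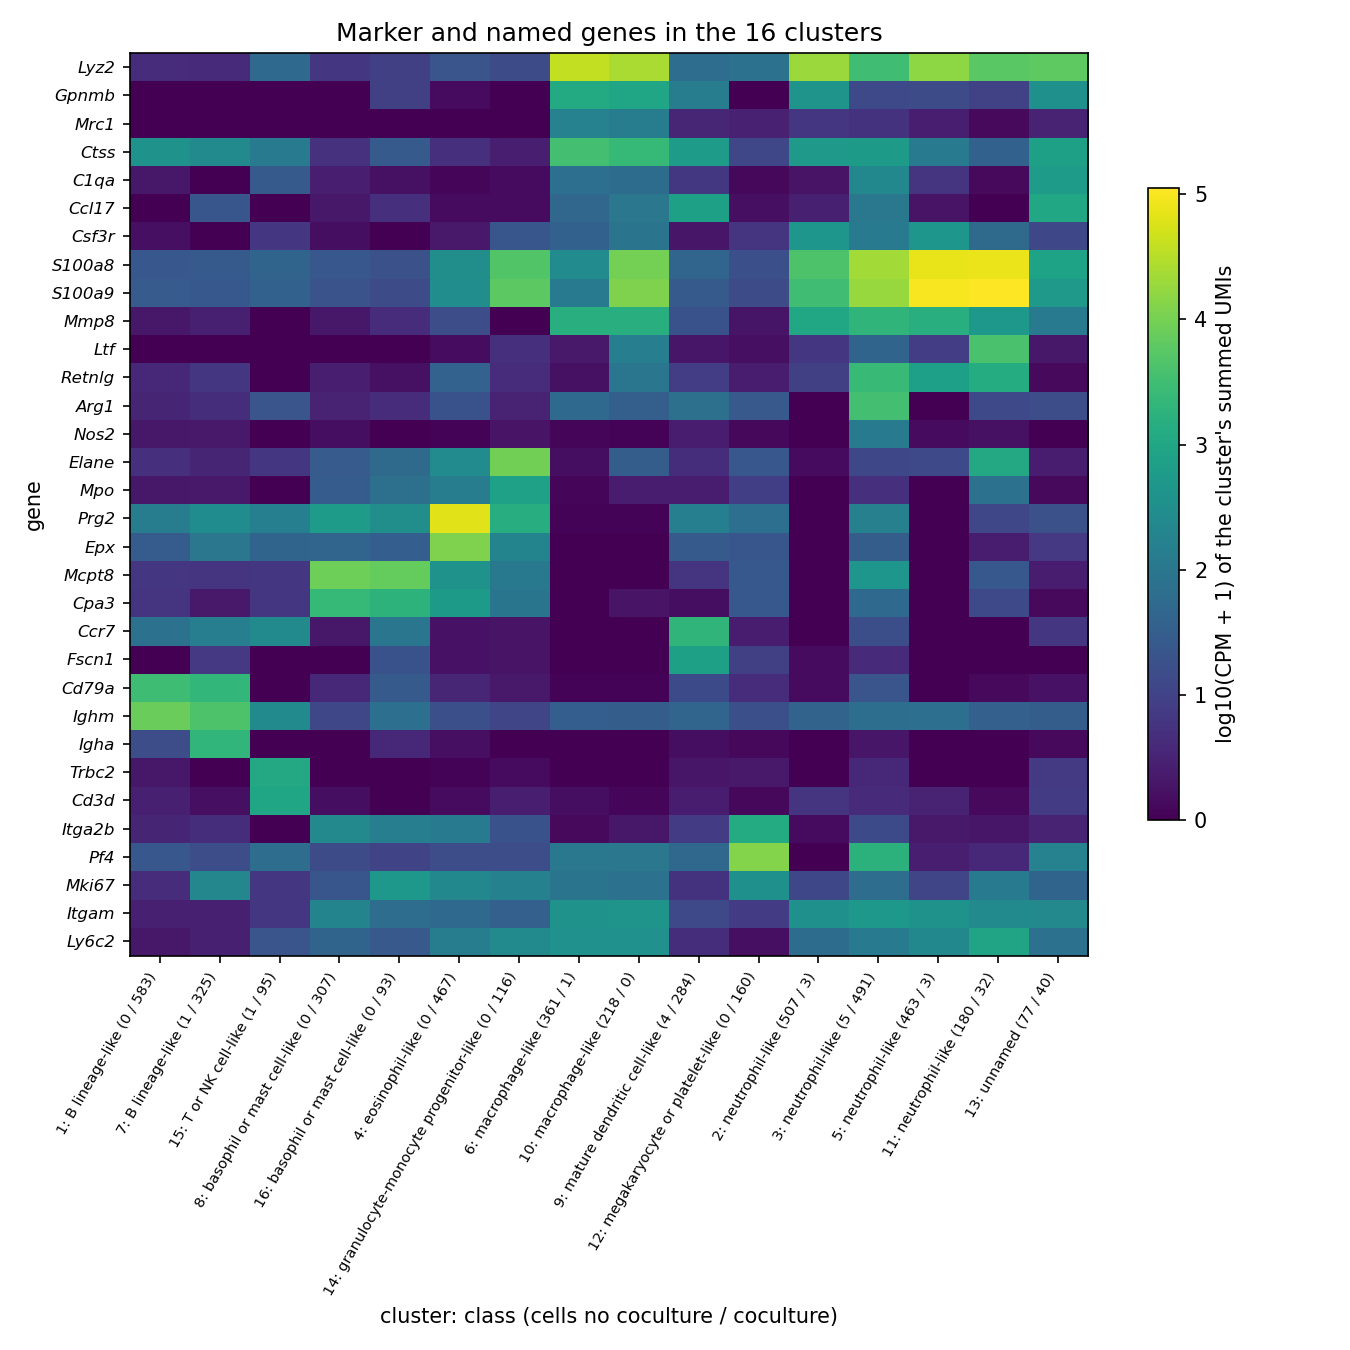
Summed level, as log10(CPM + 1), of marker and named genes (vertical axis) in each of the 16 clusters (horizontal axis), with the number of cells without coculture and in the coculture in brackets. Arg1 and Nos2 are brightest in cluster 3, which holds 491 coculture cells, and Lyz2 in macrophage-like clusters 6 and 10, which hold 361 and 218 cells without coculture.

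Summed over all cells, the coculture library was far richer in transcripts of eosinophils, basophils and B cells and poorer in several of macrophages. Of 8667 measured genes, 1103 (12.7%) were at least 2-fold higher and 1010 (11.7%) at least 2-fold lower in the coculture library, and the median log2 ratio was 0.03. Prg2, the gene of eosinophil major basic protein, stood at 18845 CPM (18795 to 18895) in the coculture library against 1 UMI without coculture, a log2 ratio of 19.00 (16.52 to 24.30), and eosinophil-like cells held 98.7% of its coculture UMIs. Epx (eosinophil peroxidase, 3298 CPM) and Prg3 (1322 CPM) had 0 UMIs without coculture and were at least 30541-fold and at least 12243-fold higher. The basophil protease genes Prss34 (3226 CPM) and Mcpt8 (1135 CPM), also at 0 UMIs without coculture, were at least 29875-fold and at least 10508-fold higher. Basophil or mast cell-like cells held 63.5% of the Prss34 UMIs and eosinophil-like cells 31.5%. Cpa3, the mast cell carboxypeptidase gene, had 8 UMIs against 424 CPM (log2 ratio 10.53, 9.55 to 11.74).

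B lineage genes followed. Iglc1, an immunoglobulin light-chain constant gene, had 1 UMI without coculture and 188 CPM in the coculture (log2 ratio 12.35, 9.87 to 17.65), and Ebf1, a B cell transcription factor gene, 2 UMIs and 129.7 CPM (log2 ratio 10.82, 8.96 to 13.86). Igha, the constant region of IgA, had 0 UMIs and 126 CPM, at least 1169-fold higher. Tcrg-C1, a T cell receptor gamma constant gene, was at least 1122-fold higher (0 UMIs and 121 CPM), but 77.4% of its coculture UMIs lay in eosinophil-like cells. Ctla2a, a cysteine protease inhibitor gene, had 5 UMIs and 571 CPM (log2 ratio 11.63), with 61.5% of its UMIs in megakaryocyte or platelet-like cells, and the beta-globin gene Hbb-bt 3 UMIs and 230 CPM (log2 ratio 11.06, 9.51 to 13.34). Iglc1 and Hbb-bt have close copies, so their own levels are uncertain.

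The genes with the lowest ratios over all cells included several known from macrophages. Lyz2, which encodes lysozyme (chromosome 10, 117277331 to 117282321), was at 24944 CPM (24885 to 25002) without coculture and 673 CPM (663 to 682) in the coculture, a log2 ratio of -5.21, and macrophage-like cells held 83.3% of its UMIs without coculture. The acute-phase gene Saa3 had the lowest ratio, 116.5 and 0.965 CPM (log2 ratio -6.92, -7.51 to -6.38). Lpl, the gene of lipoprotein lipase, was at 961.5 and 12.6 CPM (-6.25), Mrc1 at 100.2 and 1.34 CPM (-6.22), Gpnmb at 757.5 and 11.6 CPM (-6.02), and the proton pump subunit gene Atp6v0d2 at 111.5 and 2.27 CPM (-5.62). Wfdc17 was at 1645 and 41.5 CPM (-5.31), the beta-glucan receptor gene Clec7a at 236 and 7.13 CPM (-5.05), the monocyte chemokine gene Ccl2 at 105.7 and 4.07 CPM (-4.70), and the transcription factor gene Klf4 at 126.5 and 6.31 CPM (-4.33). The transporter gene Slco4a1 (188.5 and 12.3 CPM) and the kallikrein gene Klk1b11 (198.6 and 13.2 CPM, with close copies) had log2 ratios of -3.93 and -3.91. Macrophage-like cells held 65.6% of all UMIs of the library without coculture, and from 59.4% (Slco4a1) and 64.8% (Clec7a), which is below that share, to 99.2% (Mrc1) of the UMIs of these genes. The gene counts depend on the expression minimum, with 403 higher and 513 lower genes at a minimum of 50 CPM and 3824 and 1897 with only 10 UMIs asked for, and TMM factors turned the balance to 910 higher and 1264 lower genes by moving the median of all genes to -0.13.

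Myeloid effector lists had lower medians over all cells. The lysosome and proteolysis list had 24 measured members, 16 at least 2-fold lower, 0 higher and 8 between (median log2 ratio -2.08, percentile 0), among them the cathepsin gene Ctsk (-6.18) and Psap (7036 and 619 CPM, -3.51). Lipid handling had 10 lower, 1 higher and 6 between of 17 (median -1.65, percentile 0), with the sterol exporter gene Abcg1 at -3.20, Fabp4 at -2.78 and Cd36 at -2.76. Inhibitory receptors and ligands had 9 lower and 4 between of 13 (median -1.52, percentile 0), led by Sirpa (-2.86), Pilra (-2.40) and Pirb (-2.07). Fc and pattern recognition receptors had 10 lower and 4 between of 14 (median -1.51, percentile 0), with Tlr7 at -2.85 and the Fc receptor gene Fcgr1 at -2.40. The M-CSF axis and macrophage regulators had 9 lower, 2 higher and 4 between of 15 (median -1.29, percentile 0), with the M-CSF receptor gene Csf1r at -2.07 and Runx3 at 1.97. Classical monocyte genes had 7 lower, 3 higher and 4 between of 14 (median -1.22, percentile 0.01), with the chemokine receptor gene Ccr2 at -2.48, Chil3 at -2.67 and Plac8 at 4.05. Complement and efferocytosis genes had 6 lower, 1 higher and 7 between of 14 (median -0.87, percentile 0.06), with the receptor gene Axl at -3.60 and C3 at -1.74. NADPH oxidase and granule enzymes had 7 lower, 4 higher and 6 between of 17 (median -0.85, percentile 0.095), split between Ltf at -3.41 and the progenitor granule genes Ctsg at 5.22 and Mpo at 3.63. Alternative activation genes had 7 lower, 3 higher and 4 between of 14 (median -0.84, percentile 0.11), with the chemokine gene Ccl24 at 4.17 beside Mrc1. Macrophage-like cells were almost absent from the coculture library, at 1 cell, beside all of these lists.

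Lists of MHC class II presentation, costimulation, division, protein folding and a few others had higher medians over all cells. MHC class II presentation had 7 higher and 3 between of 10 (median log2 ratio 1.96, percentile 100), with H2-Ob at 4.57, H2-Oa at 3.44, the master regulator gene Ciita at 2.90 and Cd74 at 1946 and 2800 CPM (0.53). B lineage-like cells held 59.1% of the coculture Ciita UMIs and mature dendritic cell-like cells 29.7%. Costimulation and dendritic maturation had 6 higher, 1 lower and 1 between of 8 (median 2.71, percentile 100), with Ccr7 at 5.10, Cd83 at 5.06 and Fscn1 at 4.89. S phase genes had 19 higher and 16 between of 35 (median 1.07, percentile 100), with Blm at 2.08, Tyms at 1.78 and Rrm2 at 1.60, and G2/M genes 36 higher and 14 between of 50 (median 1.36, percentile 100), with Ube2c at 2.25 and Aurka at 2.10. Eosinophil-like cells, with 27.6% of all coculture UMIs, held from 31.7% (Blm) to 56.0% (Rrm2) of those of these 5 cycling genes. Unfolded protein and amino acid stress genes had 9 higher, 2 lower and 6 between of 17 (median 1.17, percentile 100), with the chaperone gene Calr at 552 and 1997 CPM (1.85) and Atf3 at -3.00. Eosinophil-like cells held 70.0% of the coculture Calr UMIs, while neutrophil-like cells held 75.9% of those of Atf3. Inflammatory cytokines and inflammasome genes had 6 higher, 4 lower and 5 between of 15 (median 0.75, percentile 99.9), with Il6 at 6.37 (10 and 864 UMIs), Cxcl3 at 4.23 and Tnf at -3.04. Cholesterol biosynthesis had 5 higher and 14 between of 19 (median 0.60, percentile 99.9), with Fdps at 1.57 and Cyp51 at 1.05, and glycolysis and hypoxia 6 higher and 20 between of 26 (median 0.44, percentile 98.2), with Ddit4 at 2.69 and Ero1l at 2.34.

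Among the remaining lists, mitochondrially encoded and iron genes had medians lower than most random lists and ribosomal protein genes a higher one, and the others were mixed or near the other genes. Suppressor-associated genes had 6 higher, 8 lower and 7 between of 21 (median log2 ratio -0.11, percentile 21.0), with the arginase gene Arg1 at 27.5 and 689 CPM (4.65), the nitric oxide synthase gene Nos2 at 2 and 654 UMIs (8.29, 6.43 to 11.34), Cybb at -3.29 and S100a9 at -2.05. Chemokines had 7 higher, 6 lower and 2 between of 15 (median 0.17, percentile 57.1), with Ppbp at 8.97, Ccl5 at 5.35 and Ccl6 at 10602 and 3802 CPM (-1.48). Prostaglandin synthesis and reception had 3 higher, 1 lower and 7 between of 11 (median 0.18, percentile 77.7), with the cyclooxygenase gene Ptgs2 at 3.24 and the prostacyclin receptor gene Ptgir at -2.41. MHC class I presentation had 1 higher and 9 between of 10 (median 0.36, percentile 87.1), with H2-Q7 at 4.26 and B2m at -0.93. Iron and oxidative stress had 7 lower, 1 higher and 12 between of 20 (median -0.48, percentile 0.88), with the ferritin genes Ftl1 at -1.76 and Fth1 at -1.31 and the transferrin receptor gene Tfrc at 2.04. Mitochondrially encoded genes had 5 lower, 1 higher and 3 between of 9 (median -1.03, percentile 0.23), with mt-Cytb at -1.90. The 26 ribosomal protein genes all lay between (median 0.56, percentile 98.6), as did the 26 oxidative phosphorylation genes (median 0.15, percentile 63.9). The type I interferon response had 2 lower and 7 between of 9 (median -0.31, percentile 13.6), with Bst2 at 0.55, and its median was 0.55 at a minimum of 50 CPM, so no direction is read. Nor is one read for immediate early and heat shock genes (2 higher, 1 lower and 13 between of 16, median 0.10, percentile 58.1; Egr1 at 2.05, Dusp1 at -1.21) or for GM-CSF and STAT5 signalling (3 lower and 12 between of 15, median 0.01, percentile 45.3; Csf2ra at -1.76, Cish at -1.42), whose medians were -0.04 and -0.13 with TMM factors. The sex-linked list had 2 measured members (1 higher, 1 between, median 1.03, percentile 64.8).

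**Figure D3:**
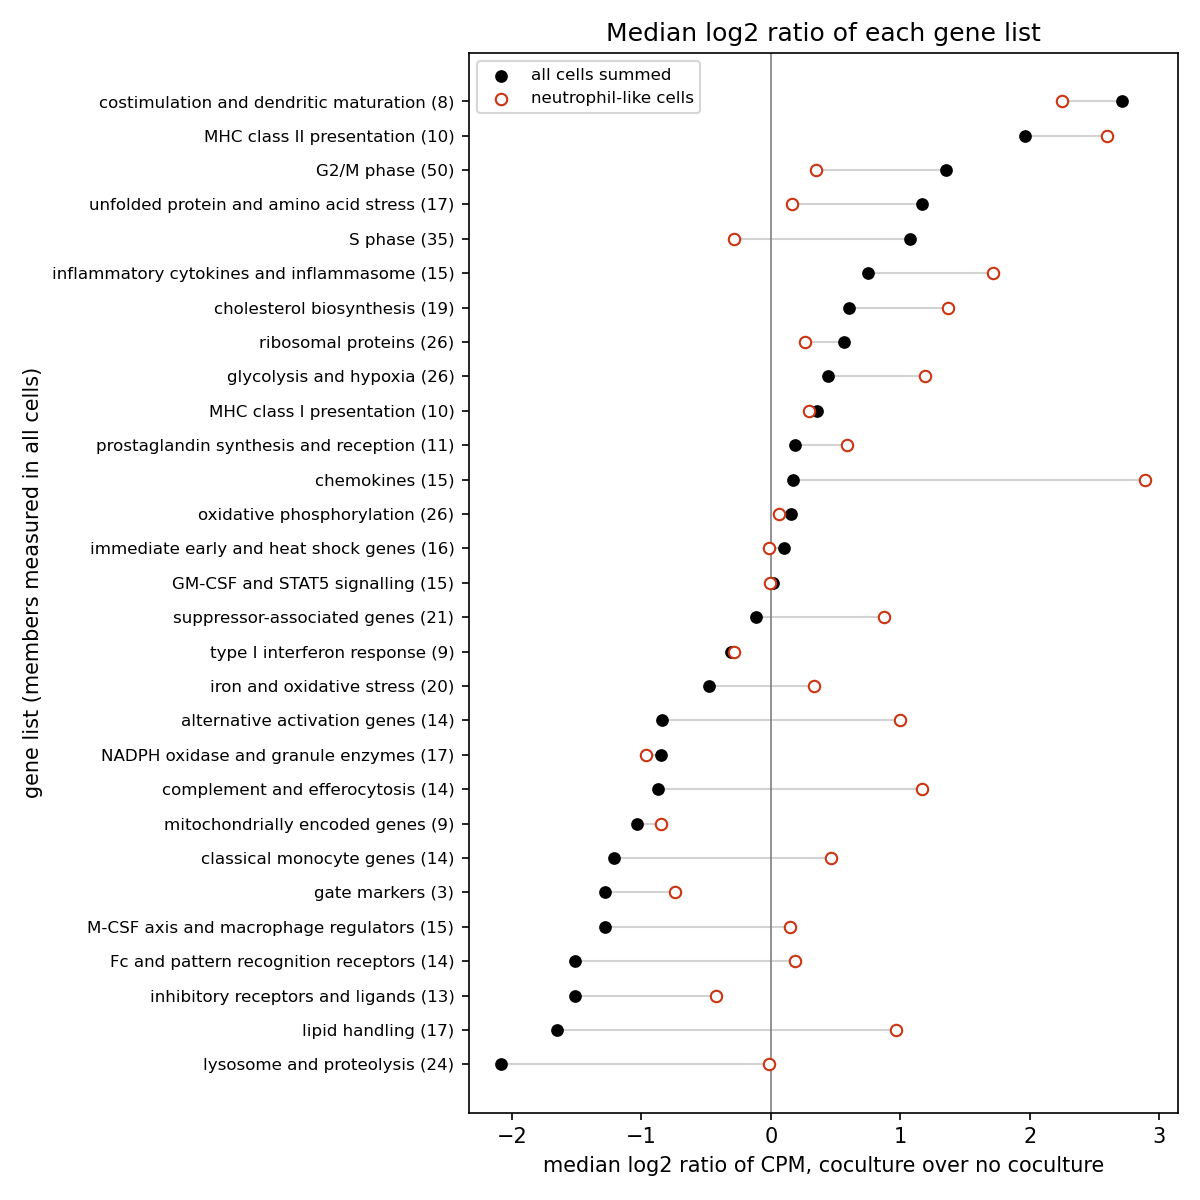
Median log2 ratio of CPM, coculture over no coculture (horizontal axis), for each gene list (vertical axis, with its measured members), over all cells (filled) and within neutrophil-like cells (open). Lysosome genes lie at -2.08 over all cells and at -0.01 within neutrophil-like cells, and chemokines at 0.17 and 2.89.

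Within the neutrophil-like class, the only one with at least 100 cells in each library (1155 and 529), Arg1 and some other suppressor-associated genes were much higher in the coculture cells, together with many chemokine genes. Several granule genes were lower in the class sum, in which granule-rich cluster 11 had a smaller share in the coculture. Arg1, whose enzyme breaks down arginine (ENSMUSG00000019987, chromosome 10, 24915221 to 24927484), had 1 UMI without coculture and 19562 in the coculture, 3266 CPM (3221 to 3312), a log2 ratio of 14.54 (12.06 to 19.85). Nos2, which encodes inducible nitric oxide synthase (chromosome 11, 78920787 to 78960254), had 1 UMI and 640 UMIs, 107 CPM in the coculture (98.7 to 115.5), a log2 ratio of 9.61 (7.13 to 14.92). Tnfrsf9, the gene of the receptor 4-1BB, had 8 and 3029 UMIs (log2 ratio 8.85, 7.87 to 10.07), and Pmepa1 1 and 1026 UMIs (10.29, 7.81 to 15.60). The platelet chemokine genes Pf4 (4 and 10100 UMIs; 11.59, 10.23 to 13.47) and Ppbp (1 and 1576 UMIs; 10.91, 8.43 to 16.21) were also among the highest, as were the basophil protease genes Prss34 (0 and 4594 UMIs, at least 1869-fold) and Mcpt8 (0 and 2580 UMIs, at least 1050-fold). The 26 cells richest in each gene, out of 529, held 98.1% of the Prss34, 98.9% of the Mcpt8 and 66.4% of the Ppbp UMIs. For Arg1 it was 33.2%, for Pf4 37.0% and for Nos2 51.6%. Prss34 reached 17727 CPM in basophil or mast cell-like cells and Pf4 12903 CPM in megakaryocyte or platelet-like cells, against 767 and 1686 CPM here, and droplets with more than 1 cell were not removed. When cells were thinned before clustering the log2 ratio of Arg1 was 9.82, and when the genes named within the class and the suppressor-associated genes were kept out of the clustering it was 14.43. Of 7752 measured genes in the class, 733 (9.46%) were at least 2-fold higher and 494 (6.37%) at least 2-fold lower, with a median log2 ratio of -0.04.

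**Figure D4:**
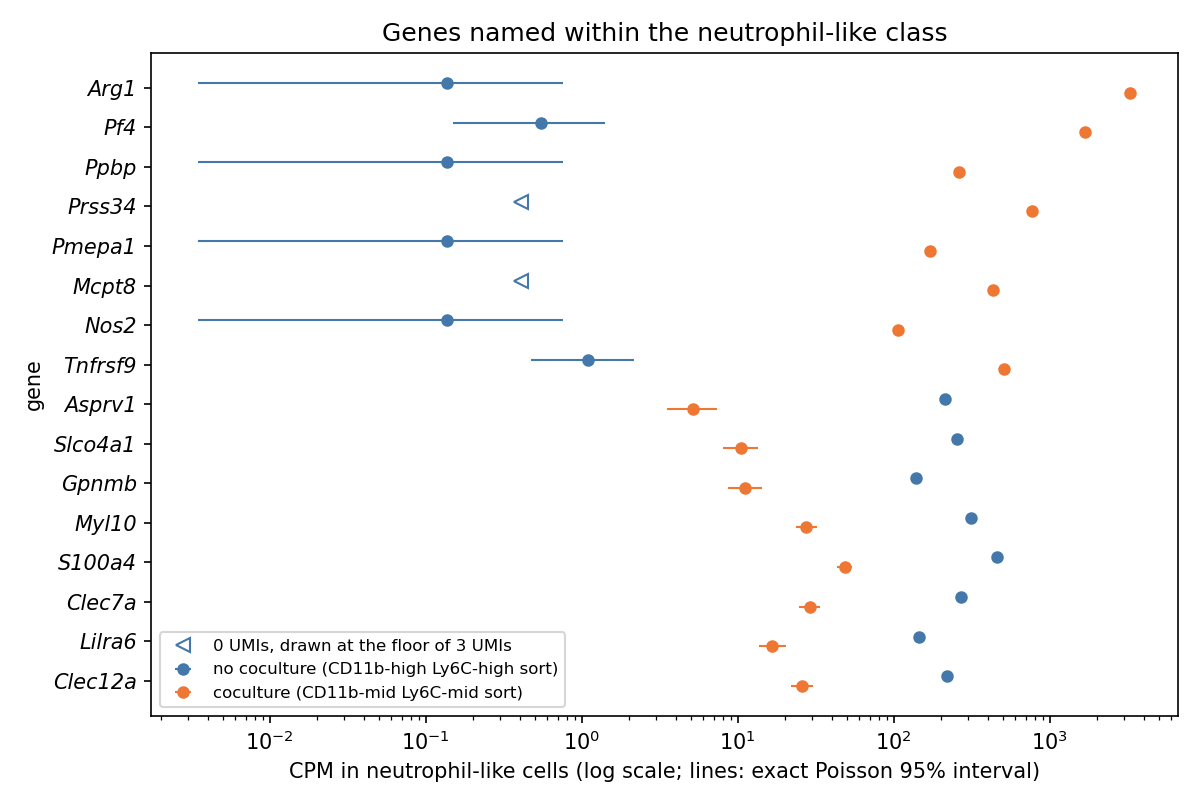
CPM in neutrophil-like cells (log axis) of the 8 genes with the highest and the 8 with the lowest log2 ratio (vertical axis) in each library, with exact Poisson 95% intervals as lines, and 0 UMIs drawn at the floor of 3 UMIs. Arg1 reaches 3266 CPM in coculture cells against 1 UMI without coculture, and Asprv1 stands at 212 and 5.18 CPM without and with coculture.

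The genes with the lowest ratios in the class were Asprv1, which encodes a retroviral-like protease (212 and 5.18 CPM, log2 ratio -5.35, -5.92 to -4.84), the transporter gene Slco4a1 (253 and 10.5 CPM, -4.59), Gpnmb (138 and 11.2 CPM, -3.62), Myl10 (312 and 27.6 CPM, -3.50), the calcium-binding protein gene S100a4 (457.5 and 48.4 CPM, -3.24), Clec7a (271 and 28.9 CPM, -3.23), Lilra6 (145 and 16.7 CPM, -3.11) and the inhibitory receptor gene Clec12a (219 and 25.9 CPM, -3.08). Gpnmb was the least stable of these, with a log2 ratio of -0.08 once clusters with tied markers were left unnamed, and Clec7a stood at -1.53 there. Itgam was higher in the coculture cells of the class (312 and 496 CPM, 0.67) and Ly6c2 lower (398 and 169 CPM, -1.24), and the gate markers as a list had 1 lower and 2 between of 3 (median -0.74, percentile 4.59). In shared cluster 11 Ly6c2 stood at 900 CPM without coculture and 800 CPM in the coculture, and Itgam at 224 and 445 CPM. That cluster held 180 of the 1155 class cells without coculture and 32 of the 529 in the coculture. The lower class value of Ly6c2 thus reflects, at least in part, the mix of clusters.

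Suppressor-associated genes within the class had 10 higher, 1 lower and 11 between of 22 (median log2 ratio 0.88, percentile 100), including the cyclooxygenase gene Ptgs2 (3.97 and 64.0 CPM, 4.01) and the heme oxygenase gene Hmox1 (58.2 and 432 CPM, 2.89), while S100a9 stood at 72755 and 24163 CPM (-1.59). Among inhibitory receptors and ligands, 2 were higher, 3 lower and 9 between of 14 (median -0.43, percentile 2.18), with the PD-L1 gene Cd274 at 50.6 and 145 CPM (1.52) and Siglece at -1.44. Chemokines had 9 higher, 3 lower and 2 between of 14 (median 2.89, percentile 100), and inflammatory cytokines and inflammasome genes 8 higher, 1 lower and 7 between of 16 (median 1.72, percentile 100). Cxcl3 and Cxcl2, which encode neutrophil-attracting chemokines, stood at 58.4 and 4078 CPM (6.13) and at 320 and 2667 CPM (3.06), Il1a at 6.21, and Il6 at 0 and 173 UMIs, at least 70.4-fold higher. The 26 richest of the 529 coculture cells held 79.8% of the Il6 and 64.6% of the Il1a UMIs, against 26.5% for Cxcl3 and 21.7% for Cxcl2. Il6 stood at 161 CPM in basophil or mast cell-like cells, against 28.9 CPM here. Classical monocyte genes had 6 higher, 5 lower and 1 between of 12 (median 0.46, percentile 98.7), with the fibronectin gene Fn1 at 5.34 and 1358 CPM (7.99), F13a1 at 4.18, Vcan at 3.32 and Ccr2 at 2.41 but Lyz2 at 13614 and 3082 CPM (-2.14). In coculture basophil or mast cell-like cells F13a1 and Ccr2 stood higher, at 271 and 190 CPM against 71.8 and 106 CPM here. Fn1 and Vcan stood lower in them than here. Droplets with more than 1 cell were not removed. Complement and efferocytosis genes had 6 higher and 6 between of 12 (median 1.17, percentile 100), led by the complement genes C1qa (6.73), C1qb (5.77) and C1qc (5.56), though 26 of the 529 cells held 84.0% of the C1qa UMIs. At resolution 1.2 these 3 genes were among the leading genes of an unnamed cluster with 127 coculture cells, outside the class. Alternative activation had 6 higher, 3 lower and 4 between of 13 (median 1.00, percentile 100), with the transglutaminase gene Tgm2 at 65.1 and 757 CPM (3.54) and Ccl17 at -3.31. NADPH oxidase and granule enzymes had 7 lower, 0 higher and 10 between of 17 (median -0.97, percentile 0), with Mpo at -2.92, lactoferrin gene Ltf at -2.90, Camp at -2.34 and Ngp at -2.31. Within shared cluster 11, Camp stood at 2572 CPM without coculture and 2605 CPM in the coculture, and Ltf at 4104 and 2344 CPM. That cluster held 180 of the 1155 class cells without coculture and 32 of the 529 in the coculture. The lower class values of Camp and Ltf thus reflect, at least in part, the mix of clusters.

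Cholesterol, glycolysis, MHC class II and costimulation lists had most members higher in the coculture neutrophil-like cells. Cholesterol biosynthesis had 14 higher and 4 between of 18 (median log2 ratio 1.37, percentile 100), with Idi1 at 2.31. Glycolysis and hypoxia had 15 higher and 11 between of 26 (median 1.19, percentile 100), with Vegfa at 46.9 and 330 CPM (2.81), Ero1l at 2.41 and Bnip3 at 2.17. Lipid handling had 5 higher, 2 lower and 6 between of 13 (median 0.97, percentile 100), with the lipid exporter gene Abca1 at 5.71, the scavenger receptor gene Msr1 at 3.98 and Lpl at -2.91. Prostaglandin genes had 4 higher and 8 between of 12 (median 0.59, percentile 99.2), with Ptgs1 at 2.11. MHC class II presentation had 8 of 8 higher (median 2.60, percentile 100), with H2-Ab1 at 28.5 and 289 CPM (3.34), and costimulation and dendritic maturation 4 higher and 2 between of 6 (median 2.25, percentile 99.9), with Cd86 at 2.98. H2-Ab1 stood at 2617 CPM in the B lineage-like and 10.5 CPM in the T or NK cell-like cells of the same library, and 26 of the 529 neutrophil-like cells held 63.1% of its UMIs.

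Most of the other lists differed less or were mixed within the class. Mitochondrially encoded genes (percentile 0.05) and G2/M genes stood further out among random lists. G2/M genes had 4 higher, 2 lower and 33 between of 39 (median log2 ratio 0.35, percentile 100) and S phase genes 2 lower and 22 between of 24 (median -0.29, percentile 3.52). At equal depth, however, the share of class cells with at least 2 G2/M UMIs was lower in the coculture. It was 68.6% (65.7 to 71.5%) without coculture and 57.2% (52.7 to 61.6%) in the coculture. The G2/M median is therefore not read as a rise across the class. Iron and oxidative stress genes had 3 higher, 1 lower and 16 between of 20 (median 0.33, percentile 97.7), with Fth1 at 1.33. MHC class I presentation had 1 higher, 1 lower and 8 between of 10 (median 0.29, percentile 89.99), unfolded protein and amino acid stress 1 higher, 4 lower and 12 between of 17 (median 0.16, percentile 92.6), with the serine synthesis gene Phgdh at -2.51 and Asns at -2.24. Fc and pattern recognition receptors had 4 higher and 10 between of 14 (median 0.19, percentile 82.2; Fcgr4 at 2.76), the M-CSF axis 4 higher, 1 lower and 11 between of 16 (median 0.15, percentile 86.6; Irf8 at 3.46, Csf1r at 2.00), and GM-CSF and STAT5 signalling 4 higher and 11 between of 15 (median -0.01, percentile 58.3; Csf2rb at 2.00). Lysosome genes had 3 higher, 3 lower and 17 between of 23 (median -0.01, percentile 46.5), immediate early genes 3 higher, 2 lower and 11 between of 16 (median -0.01, percentile 56.4; Egr1 at 3.52), the type I interferon response 4 lower and 6 between of 10 (median -0.28, percentile 10.6; Irf7 at -1.13), oxidative phosphorylation 1 lower and 25 between of 26 (median 0.06, percentile 82.1), and mitochondrially encoded genes 1 higher, 3 lower and 5 between of 9 (median -0.85, percentile 0.05). The 26 ribosomal protein genes lay between (median 0.26, percentile 80.7), and the sex-linked list had 1 measured member.

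Arg1 in the coculture library belonged almost wholly to cluster 3. Its level there was 3480 CPM (3431 to 3529), and neutrophil-like cells held 97.8% of the coculture library's Arg1 UMIs. The same cluster carried neutrophil genes such as Retnlg (2669 CPM), the collagenase gene Mmp8 (2016 CPM) and the chemokine receptor gene Cxcr2 (304 CPM), and monocyte genes such as Fn1 (1447.5 CPM), Cd14 (1279.5 CPM) and Csf1r (286 CPM), all of them chosen after the cluster had been seen. Mmp8 also stood at 1494 and 1431 CPM in macrophage-like clusters 6 and 10. Against cluster 5 without coculture, Retnlg (712 CPM there) and Mmp8 (1493 CPM) were higher in cluster 3. The neutrophil genes S100a8 (22683 against 76100 CPM), S100a9 (18738 against 100329), Csf3r (115 against 444) and Ly6g (43.7 against 74.1) were lower in cluster 3. In cluster 11, which both libraries held, Arg1 was at 1 UMI without coculture and 33 UMIs in the coculture (89.5 CPM, 61.6 to 125.8). Clusters 2 and 5 had 0 Arg1 UMIs without coculture, and the 763 Arg1 UMIs of that library were 99.9% in macrophage-like cells.

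At equal depth, 66.9% (62.5 to 71.0%) of coculture neutrophil-like cells had an Arg1 UMI and 0 of 1017 without coculture, which allows up to 0.295% of cells with an Arg1 UMI at this depth but sets no limit on cells with less Arg1 than the depth can show. B lineage-like cells, which should lack Arg1, showed 0.786% in the coculture. Over all cells the shares were 1.38% without coculture and 13.2% (11.9 to 14.5%) in the coculture. For Nos2 the neutrophil-like shares were 0% and 14.6% (11.6 to 18.1%), with 0.393% in B lineage-like cells, and for Ptgs2 0.983% and 7.82%, with 0 UMIs in B lineage-like cells (up to 0.393%). Cd274 was seen in 10.8% and 27.8% of neutrophil-like cells and in 3.28% of B lineage-like cells, and H2-Ab1 in 1.18% and 20.2%, beside 2.94% of T or NK cell-like cells (34 cells). Itgam was seen in 48.1% and 54.9% (50.4 to 59.4%) of neutrophil-like cells and in 0.131% of B lineage-like cells, but over all cells in 49.7% without coculture and 17.6% in the coculture. Ly6c2 was seen in 29.1% and 8.63% of all cells and in 0.393% of B lineage-like cells. In neutrophil-like cells its shares were 21.5% (19.0 to 24.2%) and 19.1% (15.7 to 22.9%), with overlapping intervals. Before thinning the neutrophil-like Arg1 shares were 0.0866% and 74.3%, those of Nos2 0.0866% and 31.4%, and the all-cell shares of Itgam 81.8% and 33.4%. The median depths before thinning were 4438 UMIs without coculture and 8469 in the coculture for neutrophil-like cells, 2865.5 for B lineage-like and 1884 for T or NK cell-like cells.

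Cycling genes took more of the UMIs in the coculture library. The S phase list summed to 777 CPM without coculture and 1533 CPM in the coculture (1.97-fold), and the G2/M list to 1899.7 and 4746 CPM (2.498-fold). At equal depth, 27.9% (25.8 to 30.1%) of cells without coculture and 46.4% (44.5 to 48.3%) in the coculture held at least 2 S phase UMIs. The G2/M shares were 66.0% (63.7 to 68.3%) and 72.4% (70.7 to 74.1%). The G2/M gene Mki67 was seen in 6.00% and 13.3% of cells, beside 4.59% of B lineage-like cells, which themselves include cycling cells. A cell counted for a list is not thereby a dividing cell. In neutrophil-like cells the G2/M share was 68.6% without coculture and 57.2% in the coculture, while Mki67 was seen in 3.05% and 6.79%. Among classes, the S phase share was 87.9% in progenitor-like, 73.9% in eosinophil-like and 71.1% in megakaryocyte or platelet-like cells of the coculture, 35.7% in macrophage-like cells without coculture, and 23.2% and 23.3% in neutrophil-like cells without and with coculture. Before thinning the G2/M shares were 91.7% and 90.6%, against the order of the summed CPM, so no order is read from them.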

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

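The tests of free RNA, of the B lineage-like cells, of clusters found without the named genes and of classes found without mitochondrial genes were chosen only after the results were seen, while those of depth, of the shared neutrophil-like cluster and of the mix of classes were fixed earlier.

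Barcodes left out for few genes or high mitochondrial content were set against each other between the libraries, since the comparisons do not use them. In the coculture library they held eosinophil markers at 17617.5 CPM, against 19.6 CPM in those of the library without coculture, B lineage markers at 8699 CPM against 467, and megakaryocyte or platelet markers at 7777 CPM against 76.6. Mature dendritic cell markers stood at 2454 CPM against 169, basophil or mast cell markers at 1852 CPM against 116, and erythroid markers at 93.8 CPM (12 UMIs) against 1.96 CPM (1 UMI). Clusters of these classes were among the kept coculture cells, except erythroid, for which no cluster was named. Other sets lay closer together, among them dendritic cell markers (9497 CPM in the coculture against 1192) and, in the other direction, neutrophil (18516 against 31894 CPM), macrophage (1532 against 5524 CPM) and monocyte markers (563 against 2653 CPM).

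Arg1 was at 3266 CPM in coculture neutrophil-like cells and at 1 UMI in those without coculture. Free RNA would spread it over all coculture clusters, but the highest other cluster, the coculture cells of shared cluster 11, carried 2.57% of the level of cluster 3. Depth alone is argued against by a difference of 66.9 percentage points in cells with an Arg1 UMI at equal depth. A rise to a like level was not seen in the state of cluster 11, at the same 2.57%, nor in the shared cluster found with Arg1 and the other named genes kept out of the clustering, at 2.61% (1.82 to 3.62%). There only 4 of its 32 coculture cells held the 35 Arg1 UMIs, and droplets with more than 1 cell were not removed. Other states could not be looked at, since clusters 2 and 5 held 3 coculture cells each. Genes that vary with Arg1 could still shape both clusterings and draw cells with Arg1 out of the shared cluster. Whether every state would show a rise is therefore not decided. A hypothesis that remains is that 1 coculture state may carry Arg1, and because gate, medium and library go with the coculture, which of them it follows stays open.

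B lineage-like cells made up 30.3% of a sort on CD11b-mid Ly6C-mid cells. Only 0.131% of them had an Itgam UMI at equal depth, which met the criterion set for cells sorted without their own CD11b transcript. That criterion restates the observation, so it does not show how the cells entered the gate. Droplets that also hold a neutrophil-like cell are argued against as the main source, because 5.07% (46 of 908) reached the median depth of coculture neutrophil-like cells. Antibody bound without the antigen, a wide gate and protein without transcript were not tested.

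Barcodes over 10% mitochondrial UMIs made up 15.5% of the library without coculture and 2.87% of the coculture library. A different mix of the named classes is argued against, because within neutrophil-like barcodes the shares were 19.8% (17.8 to 22.0%) and 1.10% (0.404 to 2.37%), a difference of 18.7 percentage points. Class membership there partly follows mitochondrial content, and unnamed barcodes had 33.3% and 48.3%, but with mitochondrially encoded genes left out of clustering and naming the neutrophil-like shares were 21.8% (19.8 to 24.0%) and 1.31% (0.528 to 2.68%), a difference of 20.5 percentage points. Of the 324 such barcodes without coculture 288 lay in 1 shallow cluster (366 and 1 barcodes), so a different mix of states inside the class stays open. Culture, sort and handling of the library differ together and stay open too.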

How the results depend on the processing

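The tied-marker and named-gene alternatives were chosen only after the results were seen. Of the values that answer a comparison, 109 stayed within their interval or within 1.5 times under an alternative, and 31 moved, and of the others 504 stayed and 223 moved; where no reason is given the cause was not tested. Changes of sign were seen 7 times, all in medians of all genes or of lists for which no direction is read (immediate early, GM-CSF and STAT5, type I interferon). All deposited barcodes gave 66.7% neutrophil-like and 26.9% macrophage-like cells without coculture, and a share counted for the G2/M list of 62.7% there. Stricter filters gave 60.7% neutrophil-like and 34.4% macrophage-like cells without coculture, and 15.4% basophil or mast cell-like cells in the coculture. Without the 5% deepest cells, which removes more of the deeper classes, macrophage-like cells were 28.0%, eosinophil-like cells 14.2% and the G2/M share without coculture 63.4%. A minimum of 50 CPM, by testing fewer genes, left 403 higher and 513 lower genes, TMM factors gave 910 and 1264, both turning the balance of 1103 and 1010, and 10 UMIs alone gave 3824 and 1897. The coculture neutrophil-like share was 14.8% at resolution 1.2 and 16.03% with 1000 variable genes. The share without coculture was 60.9% without S and G2/M genes, 61.1% without the named genes, 57.7% with thinned cells (macrophage-like 34.3%, coculture B lineage-like 28.3%) and 35.7% with tied clusters unnamed. The Arg1 share of all coculture cells was 11.1% at 1036 UMIs and 15.5% unthinned. G2/M shares (no coculture, coculture) were 36.8% and 47.7% at 1036 UMIs, 91.7% and 90.6% unthinned (in the other order), 88.2% and 89.6% for 1 UMI, and 26.6% and 41.0% for 4 UMIs, by construction of the rule. Depth limits what can be said of genes with 0 UMIs. No paired analysis was possible because each group has 1 library.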

Other observations

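The genes, cells and clusters described in this part were chosen only after the results were seen, and no test was run on them. Basophil or mast cell-like cells were the main source of Il6 and Il4 in the coculture library. Il6, which encodes interleukin 6, stood at 161 CPM in them, at 30.5 CPM in megakaryocyte or platelet-like and at 28.9 CPM in neutrophil-like cells, and 62.6% of the library's 864 Il6 UMIs were theirs. Il4 stood at 112 CPM in them and at 20.9 CPM in eosinophil-like cells. Mature dendritic cell-like cells carried the most Cd274, the PD-L1 gene, at 432 CPM, against 145 CPM in neutrophil-like cells of the coculture.

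The unnamed cluster 13 differed between the libraries (77 and 40 cells). In its coculture cells the complement gene C1qa was at 2512 CPM against 59.2 CPM (log2 ratio 5.41) and Ccl24 at 598 against 8.46 CPM (6.14), while the chemokine genes Ccl4 (3630 and 12.2 CPM, -8.22) and Ccl3 (1582 and 29.6 CPM, -5.74), Lpl (2016 and 27.9 CPM, -6.18) and Chil3 (2279 CPM and 1 UMI, -10.35, -15.66 to -7.87) were lower. With cells thinned before clustering, the unnamed cells formed 1 cluster of 113 cells without coculture and 1 in the coculture, led by Ccl4 and Ptx3, and another of 10 and 34 cells, led by C1qa and Asgr2.

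A few coculture cells carried connective tissue transcripts. With at least 10 UMIs over 6 matrix genes (Col1a1, Col1a2, Col3a1, Dcn, Lum and Sparc) there were 9 of 3000 coculture cells (0.300%, 0.137 to 0.569%) and 0 of 1817 without coculture (up to 0.165%). Of these, 8 fell in cluster 12, so the megakaryocyte or platelet-like class holds some cells of another kind. They had a median of 28912 UMIs, Sparc at 3281 CPM against 0.695 CPM in the other coculture cells, Timp1 at 4738 CPM, 0 UMIs of the blood cell gene Ptprc, and 1.41% mitochondrial UMIs by the mouse annotation. They also held 163 of the library's 584 Ptgs2 UMIs. The counts are against the mouse genome only and human transcripts were not analysed here, so the species of these cells is not settled.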
